A study of Homo sapiens with 4 samples.

How the data were processed

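The series holds H3K27ac HiChIP libraries from IMR90 human lung fibroblasts. HiChIP joins DNA ends that lie close together in fixed nuclei, then pulls down the joined fragments with an antibody, here against histone H3 acetylated at lysine 27, a mark of active enhancers and promoters. Per the labels' protocols, chromatin was fixed with formaldehyde, cut with MboI and tagmented with Tn5, and the libraries were amplified by PCR. There are 4 libraries, 1 per group: control cells, and senescent cells carrying a control hairpin (shcontrol), a hairpin against METTL3 or a hairpin against METTL14. Groups were taken from the treatment label for the control library and from the genotype label for the others. The label used for the control library names no hairpin, so control and senescent shcontrol may also differ in carrying one. The treatment protocol of the labels names METTL4 where the genotype label and the series design name METTL14, and the genotype label was followed. Senescence was induced through an inducible RAS fusion protein, per the labels' protocols.

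Per the submitters' processing notes, HiC-Pro version 3.1.0 and the hg19 build were used; the step that called the interactions is not given in the sources used here. Each deposited file lists pairs of anchor regions on the same chromosome with 8 columns and no header. The seventh column was read as the deposited count of paired-end tags (PETs) that join both anchors, a raw count with no normalization. The eighth column runs from 0 to at most 0.997 and was read as the authors' false discovery rate, a q-value for each interaction. Its name is not given in the sources used here. It steps sharply with span: among interactions of exactly 4 PETs, none between 20 and 120 kb had a value of 0.01 or less in any library, and all from 160 kb on did. The first called interactions of 4 PETs spanned 140 to 160 kb in the shMETTL14 library and 120 to 140 kb in the other libraries. The files list interactions with spans from 5000 bp to just under 2000 kb, so longer contacts and contacts between chromosomes were not analysed here. The span is the distance between anchor midpoints.

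Anchor positions match a count from 0 with an open end: starts of one anchor set coincide with ends of the other at 508 boundaries, and none is shifted by 1 bp. Positions are given here counted from 1. The 3 senescent libraries use 1 common set of 55317 anchors that covers 232 Mb, and 51757 of these occur in all 3 libraries. The control library uses a different set of 66743 anchors that covers 318 Mb. Only 4122 anchors have the same ends in both sets. Overlapping anchors were therefore merged into 79742 regions, of which 38038 hold anchors of both sets, 27592 hold anchors of the control set only and 14112 hold anchors of the senescent set only. Control and senescent libraries were compared over the 38038 shared regions, and senescent libraries over every region with a senescent anchor (52150). A wider anchor collects more PETs, and an anchor with more signal may also have been called wider, which was not tested. The length that each set covers is therefore given beside differences between the control and a senescent library.

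Gene names could not be attached to anchors. The gene table given for the series is on GRCh38.p14 while the files are on hg19 (their anchors on chromosome 1 reach position 249230895), and positions were not converted between builds. The 15 gene lists and the individual genes chosen before the data were examined were therefore not analysed here, and the anchor version of the design, also fixed before the data were examined, was used. The rule for named anchors was the 10 with the highest and the 10 with the lowest log2 ratio per comparison among anchors that met the size rule and had at least 100 PETs over both libraries.

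Called loops are interactions with at least 4 PETs and a deposited false discovery rate of at most 0.01. The number of called loops grows with depth, so counts were repeated after PETs of every library were drawn without replacement down to the smallest total, 552029 (seed 1). Thinning changed the PET counts only, and each interaction kept the false discovery rate of its full library, which could not be recomputed since its method is not given in the sources used here. A called loop of one library was found in another if both anchors overlapped those of a called loop there by at least 1 bp. An anchor with 5 or more called loops was counted as a hub. For contact change, PETs with an end in a merged anchor were counted once per anchor and scaled to 1000000 PETs of the library. The log2 ratio used a pseudocount of 1 per 1000000. The size rule asked for at least a 2-fold difference on that scale, an exact conditional binomial 95% interval of the ratio that excludes 1, and at least 50 PETs over both libraries. Windows of 1 Mb were compared in the same way with at least 200 PETs and a pseudocount of 10 per 1000000; for control against senescent shcontrol only PETs with both ends in shared anchors entered. Single loops were compared with at least 20 PETs over both libraries. The windows and the single loops were chosen after seeing the data.

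Each group has 1 library, so no test across conditions could be run and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals, and ratios carry exact conditional binomial intervals. PCR reads without molecular identifiers are not independent molecules, and these intervals cover counting error only, not the spread between cultures or library preparations. Depth was 552029 to 998378 PETs per library, and between 62.2% and 66.2% of the listed interactions rest on a single PET.

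The senescent shcontrol library enters both knockdown comparisons and the choice of anchors that are higher in senescence. Values with no effect were therefore simulated 100 times by drawing the 3 senescent libraries from their pooled proportions. In addition, the PETs of that library were split at random into 2 parts, 1 for each use, which removes shared counting error but not other variation of that library. The anchor comparison was tested on simulated data before use, with 200 anchors changed by known folds. In the simulation of senescent shcontrol against control, run on 38038 anchors, 48 of 50 anchors raised 4-fold and 50 of 50 lowered 4-fold met the size rule, as did 23 of 50 raised 2-fold, 23 of 50 lowered 2-fold and 57 of 14909 left alone. For shMETTL3 against shcontrol, run on 52150 anchors, these were 50 of 50, 50 of 50, 26 of 50, 19 of 50 and 46 of 12079. For shMETTL14 against shcontrol, also on 52150 anchors, they were 50 of 50, 49 of 50, 24 of 50, 18 of 50 and 68 of 15968. For shMETTL14 against shMETTL3 they were 50 of 50, 46 of 50, 20 of 50, 25 of 50 and 64 of 16578.

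Alternatives covered the PET minimum, the false discovery rate limit, thinning to equal PETs, the minimum span, the overlap rule, median-of-ratios and TMM scaling, the pseudocount and the minimum number of PETs. Calling without the false discovery rate, counting only PETs with both ends in shared anchors, restricting to anchors with the same ends and dividing by covered length were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors only.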

Results

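The series maps contacts between acetylated regions in control IMR90 fibroblasts and in IMR90 cells driven into senescence, a lasting arrest of the cell cycle, with METTL3, METTL14 or neither knocked down. METTL3 and METTL14 are the subunits of the enzyme complex that writes N6-methyladenosine on RNA, with METTL3 as the catalytic one. The series title ties METTL3 to chromatin contacts in senescence, so the comparisons are senescent shcontrol against control, each knockdown against senescent shcontrol, and the knockdowns against each other. The control library holds 998378 PETs in 432400 interactions, senescent shcontrol 552029 in 258943, shMETTL3 623930 in 270754 and shMETTL14 936492 in 368291. Each group is a single library, so differences have no replicate check and are differences between libraries. The depletion of METTL3 or METTL14 itself was not measured in these files.

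Across merged anchors the 3 senescent libraries resembled each other far more than any of them resembled the control library. Over 6783 shared anchors with at least 200 PETs in all libraries together, Pearson's r of log2 PETs per 1000000 was 0.897 between shcontrol and shMETTL3, 0.889 between shcontrol and shMETTL14 and 0.908 between the knockdowns. It was 0.383, 0.318 and 0.332 between control and senescent shcontrol, shMETTL3 and shMETTL14. Over the 318 such anchors with the same ends in both anchor sets, r was 0.863, 0.860 and 0.873 among the senescent libraries and 0.644, 0.610 and 0.633 against the control. These correlations are across anchors, which are not independent replicates.

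In senescent shcontrol against control, PETs differed at many loci. PETs at an anchor can vary with its acetylation as well as with contact, and these were not separated here. Several 1-Mb windows had several times the PETs of the control although the covered length there differed far less between the anchor sets. On chromosome 4 from 74 to 75 Mb, singled out after its values were seen, the share of PETs was 4.78-fold that of the control library (95% interval 4.22 to 5.43, 1058 against 322 PETs), with 148 kb covered by the senescent set and 137 kb by the control set. The neighbouring window from 75 to 76 Mb stood at 3.63-fold (3.17 to 4.18, 201 against 166 kb covered), chromosome 8 from 24 to 25 Mb at 3.39-fold (2.76 to 4.17, 50.9 against 46.4 kb), and chromosome 6 from 138 to 139 Mb at 3.30-fold (2.93 to 3.72, 160.5 against 148 kb). The highest ratios came with more covered length: chromosome 20 from 7 to 8 Mb had 8.97-fold (6.93 to 11.8) with 71.2 against 39.1 kb covered, and chromosome 2 from 146 to 147 Mb 7.16-fold (5.69 to 9.10) with 72.2 against 45.8 kb. Of 1489 windows with enough PETs, 51 were at least 2-fold higher in senescent shcontrol and 26 at least 2-fold lower.

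Among single anchors, the region on chromosome 6 from 138008075 to 138022537 had 145 PETs in senescent shcontrol and 4 in control, a log2 ratio of 5.72. On chromosome 2, the anchors from 113590140 to 113601631 and from 113622315 to 113646823 had 214 against 11 and 398 against 24 PETs, log2 ratios of 5.02 and 4.85. The anchor on chromosome 11 from 102712646 to 102725723 had 158 against 11 PETs and a log2 ratio of 4.58, and the one on chromosome 17 from 46312624 to 46325422 had 107 against 5 and a log2 ratio of 5.02. The senescent set covered each of these more fully. Per covered kb the log2 ratios were 3.49 for the chromosome 6 anchor, 3.31 and 2.42 for those on chromosome 2, 2.85 on chromosome 11 and 2.51 on chromosome 17. The remaining anchors among the 10 highest lie on chromosomes 3, 7, 8 and 20, the last with 2 anchors, and their log2 ratios were 4.40 to 4.81, or 1.93 to 3.38 per covered kb.

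Lower in senescent shcontrol were the anchors on chromosome 12 from 110472345 to 110482898 (2 against 125 PETs, log2 ratio -4.77), chromosome 2 from 30452291 to 30490134 (4 against 218, -4.73), chromosome 5 from 14460916 to 14473314 (2 against 112, -4.61) and chromosome 16 from 69303023 to 69312596 (2 against 108, -4.56) and from 16063293 to 16085445 (7 against 315, -4.53). Per covered kb these 5 stood at -2.92, -1.14, -2.48, -2.85 and -1.60. Among windows, chromosome 19 from 6 to 7 Mb was lowest at 0.269 of the control value (0.192 to 0.369, 46.5 against 100.3 kb covered). Chromosome 6 from 27 to 28 Mb stood at 0.359 (0.314 to 0.410, 65.5 against 132 kb), and chromosome 5 from 13 to 14 Mb at 0.307 (0.227 to 0.409, 27.8 against 36.6 kb).

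Of 15109 shared anchors with enough PETs, 2308 met the size rule as higher in senescent shcontrol and 2324 as lower, 30.7% in all, where simulated counting error alone gave 0.463%. The log2 ratio of PETs followed the log2 ratio of covered length across these anchors (Pearson's r 0.776), and across windows (0.808). Divided by covered length, 2453 anchors were higher and 367 lower, with no centring and a median log2 ratio of 0.36. Of the anchors chosen by PETs alone, 1574 of the 2308 and 350 of the 2324 also met the rule per covered kb. TMM scaling moved the median log2 ratio of all these anchors to -0.11 and gave 1990 higher and 2719 lower. Anchors with the same ends in both sets had a median of 0.44, with 162 of 829 higher and 15 lower. Once centred on that median, 53 were higher and 46 lower, and such centring pulls the counts toward balance by construction. The balance of higher and lower anchors thus depended on the measure, with 49.8% higher by PETs and 87.0% per covered kb. Division by length was not a common offset. The median log2 ratio of covered length was 0.357 at the higher anchors, -1.19 at the lower and -0.305 at those that were neither. All 20 named anchors, chosen for extreme ratios, kept their direction.

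**Figure D1:**
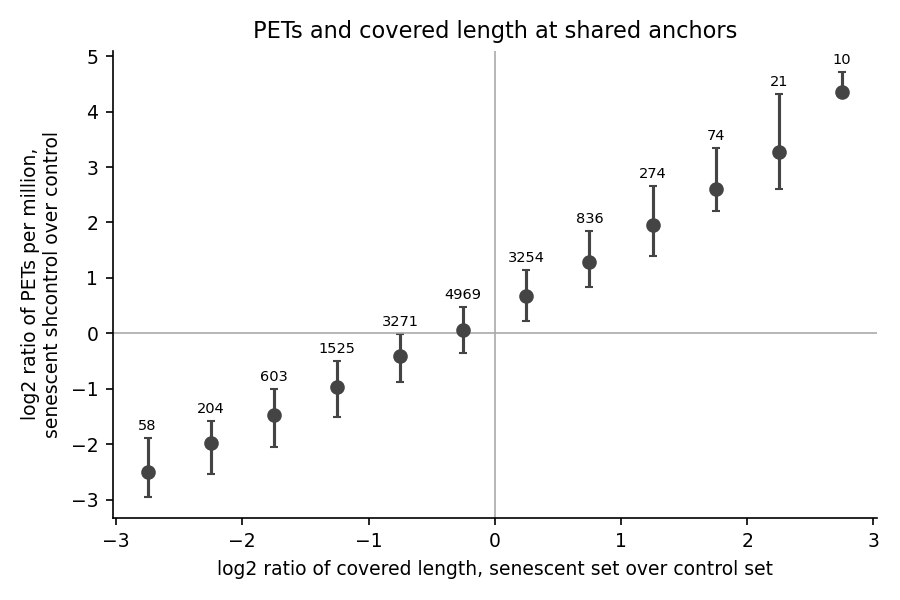
Log2 ratio of PETs per 1000000 (senescent shcontrol over control, vertical axis) against log2 ratio of covered length (senescent over control anchor set, horizontal axis) at shared anchors with at least 50 PETs, in bins of 0.5: points are medians, bars run from the lower to the upper quartile and the numbers are anchors per bin. The median runs from -2.50 in the lowest bin to 4.36 in the highest, and is 0.06 for the 4969 anchors just below equal length.

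By span, senescent shcontrol had larger shares of PETs at both ends of the range. PETs spanning 1 to 2 Mb made up 6.03% of its total (5.97 to 6.10) and 5.33% of the control total (5.29 to 5.37), a ratio of 1.13 (1.12 to 1.15). At 5 to 20 kb the ratio was 1.15 (1.14 to 1.15) and it was 0.932 (0.924 to 0.940) at 50 to 100 kb and 0.930 (0.922 to 0.938) at 100 to 200 kb. With both ends in shared anchors the ratio was 1.25 at 5 to 20 kb and 1.12 at 1 to 2 Mb. The control uses another anchor set. PETs with both ends in a single merged anchor made up 3.98% in senescent shcontrol and 0.865% in control. The difference at 5 to 20 kb was therefore not separated from the anchor sets. For all PETs at 100 kb or more the shares were 45.9% and 46.7%, a ratio of 0.982 (0.977 to 0.986), which became 1.01 when spans under 20 kb were left out. In interactions of at least 4 PETs, the share at 500 kb or more was 1.60% in senescent shcontrol and 2.14% in control, but at equal depth the ratio was 1.00 (0.956 to 1.05).

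The shMETTL3 library had a smaller share of long-span PETs than senescent shcontrol, and the ratio was lower in each longer bin from 100 kb on. Its share of PETs was 1.08 times that of shcontrol at 5 to 20 kb (1.07 to 1.09), 0.973 at 100 to 200 kb (0.964 to 0.983), 0.926 at 200 to 500 kb (0.917 to 0.934), 0.891 at 500 kb to 1 Mb (0.879 to 0.902) and 0.817 at 1 to 2 Mb (0.805 to 0.830). PETs at 100 kb or more made up 42.2% of the shMETTL3 library (42.1 to 42.3) and 45.9% of shcontrol (45.7 to 46.0). The PET-weighted median span was 69.7 kb, against 82.6 kb in shcontrol, 75.5 kb in shMETTL14 and 86.6 kb in control.

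The shMETTL14 library had a different profile. Its share was 0.917 times that of shcontrol at 100 to 200 kb (0.909 to 0.925) and 0.946 at 200 to 500 kb (0.938 to 0.954), but 1.04 at 500 kb to 1 Mb (1.02 to 1.05) and 1.05 at 1 to 2 Mb (1.04 to 1.07). At 100 kb or more it was 44.4% (44.3 to 44.5). Set against each other, shMETTL14 had 1.29 times the share of shMETTL3 at 1 to 2 Mb (1.27 to 1.30). In interactions of at least 4 PETs at equal depth, the ratio at 500 kb or more was 0.754 (0.719 to 0.790) for shMETTL3 over shcontrol and 0.992 (0.949 to 1.04) for shMETTL14 over shcontrol, so a higher share in shMETTL14 was not detectable there. Without thinning, at unequal depth, the shMETTL14 ratio in such interactions was 1.43 (1.38 to 1.48).

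**Figure D2:**
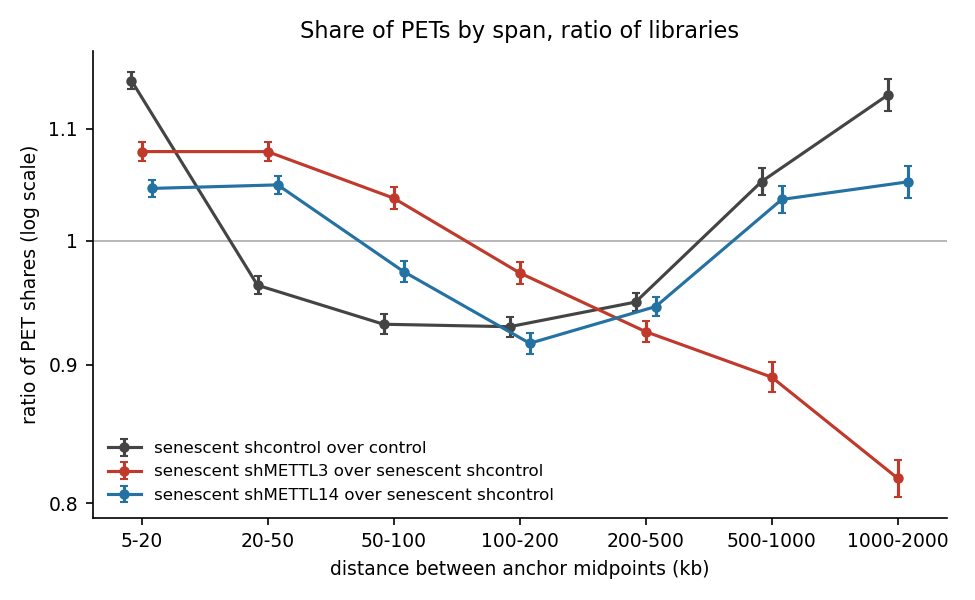
Ratio of the share of PETs (vertical axis, log scale) in each bin of the distance between anchor midpoints (horizontal axis, kb) for 3 comparisons of libraries, with bars for exact 95% counting intervals. The shMETTL3 over shcontrol ratio goes down from 1.08 at 5 to 20 kb to 0.817 at 1 to 2 Mb, while shMETTL14 over shcontrol lies above 1 from 500 kb on.

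The chromosome 4 window from 74 to 75 Mb, high in senescent shcontrol, was lower in both knockdown libraries. Its share of PETs in shMETTL3 was 0.563 of that in shcontrol (0.520 to 0.609, 1028 and 1616 PETs of all anchors) and in shMETTL14 0.709 (0.663 to 0.758, 1943 PETs). Of its 25 anchors with enough PETs, 25 were lower in shMETTL3 and 23 in shMETTL14, whatever the size of the difference. Anchors of the window share PETs and the same shcontrol library, so these counts are not independent of each other or of the window ratio. The anchors from 74552744 to 74557867, from 74766424 to 74769613 and from 74880737 to 74887222 were among the 10 lowest of the shMETTL3 comparison, with log2 ratios of -1.17, -1.10 and -1.21. In shMETTL14, the anchor from 74869987 to 74874150 was among the 10 lowest at -1.29. Chromosome 4 as a whole held 4.58% of PETs in shcontrol, 4.16% in shMETTL3, 4.57% in shMETTL14 and 4.12% in control.

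**Figure D3:**
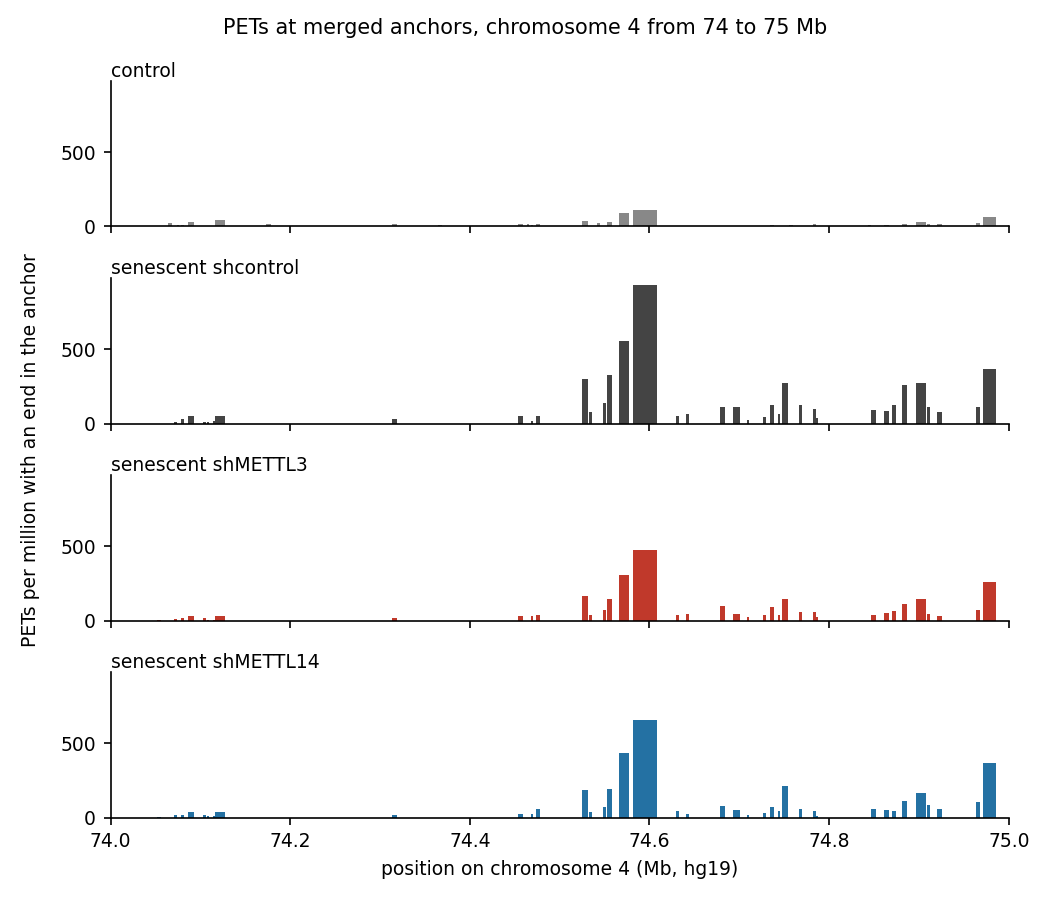
PETs per 1000000 with an end in each merged anchor (vertical axis) along chromosome 4 from 74 to 75 Mb (horizontal axis, hg19) in the 4 libraries, 1 panel each on a common scale, with bar widths to the scale of the anchors. Anchors held by 1 anchor set alone are 0 by construction in libraries of the other set, so empty positions there do not show absent contact. The window held 322 shared-anchor PETs in control and 1058 in senescent shcontrol, and its share was 0.563 of shcontrol in shMETTL3 and 0.709 in shMETTL14.

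The neighbouring window from 75 to 76 Mb stood at 0.845 of shcontrol in shMETTL3 (0.769 to 0.928) and 0.948 in shMETTL14 (0.872 to 1.03), and other windows that were high in senescence differed too. Chromosome 2 from 113 to 114 Mb, which holds both chromosome 2 anchors named above, stood at 1.04 of shcontrol in shMETTL3 (0.965 to 1.13) and 0.916 in shMETTL14 (0.851 to 0.986). Chromosome 21 from 39 to 40 Mb was at 1.00 in shMETTL3 (0.920 to 1.09) and at 0.554 in shMETTL14 (0.506 to 0.607). Chromosome 7 from 41 to 42 Mb was higher in both, at 1.57 (1.47 to 1.68) and 1.19 (1.12 to 1.27). Of the 51 windows, 31 (60.8%) were lower in shMETTL3 and 36 (70.6%) in shMETTL14. With no effect of either knockdown, the shared shcontrol library alone gave 57.1% (41.9 to 75.8 over 100 simulations) and 57.5% (45.3 to 71.2). Intervals lay below 1 in 19 (37.3%) and 21 (41.2%) of them and above 1 in 4 and 5. Over all windows intervals lay below 1 in 19.3% and 15.4%, and in at most 9.38% and 11.3% of windows chosen the same way in simulations of counting error alone. These shares depend on the PETs per window, which were not matched. The median log2 ratio of the 51 windows was -0.04 in shMETTL3, as over all 1600 windows (-0.04), and -0.10 in shMETTL14, against 0.02 over all 1765. The shared shcontrol library enters the choice of these windows.

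At the level of anchors, knockdown libraries differed from senescent shcontrol less than shcontrol differed from control. For shMETTL3, 229 of 12279 anchors were higher and 162 lower by the size rule, 3.18% in all, where simulated counting error gave 0.486%. For shMETTL14, 451 of 16168 were higher and 221 lower, 4.16% against 0.437%. With at least 200 PETs 10 were higher and 3 lower in shMETTL3, while the balance turned in shMETTL14, with 5 higher and 14 lower. The SD of the log2 ratio across anchors was 0.45 and 0.48, against 1.09 for senescent shcontrol over control, which compares different anchor sets. The latter was 0.71 per covered kb, and 0.66 over anchors with the same ends in both sets, where the knockdowns had 0.45 and 0.47. No 1-Mb window differed 2-fold in either knockdown comparison, out of 1600 and 1765. Among loops with at least 20 PETs, 257 of 6706 were higher and 158 lower in shMETTL3, and 355 of 9212 were higher and 365 lower in shMETTL14. No value from counting error alone is given for loops. For anchors with at least 20 PETs it was 1.86% in shMETTL3 and 1.70% in shMETTL14, so a part of these loops can come from counting error.

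**Figure D4:**
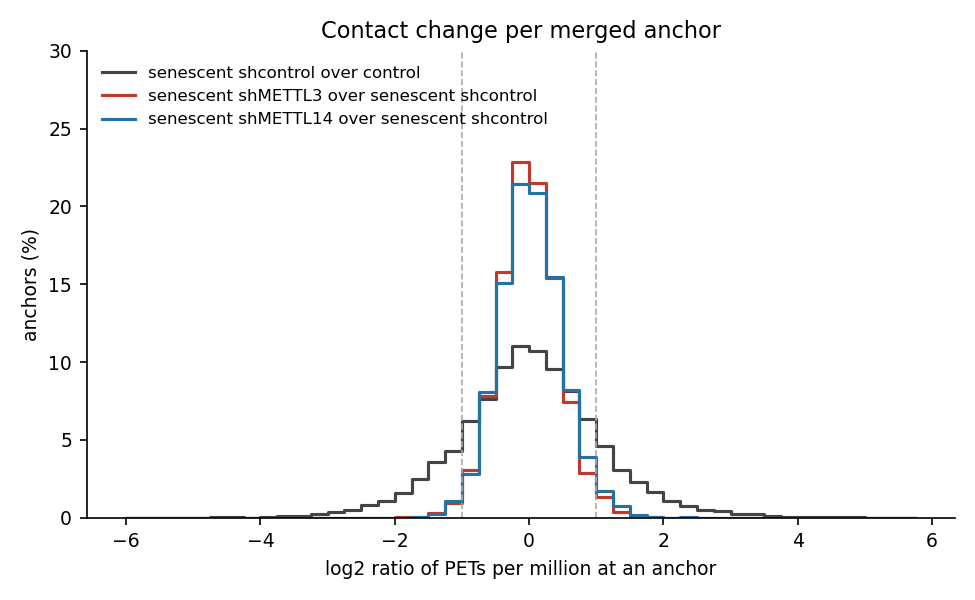
Distribution of log2 ratios of PETs per 1000000 over merged anchors with at least 50 PETs (horizontal axis, bins of 0.25) as the percentage of anchors (vertical axis) for 3 comparisons, with dashed lines at 2-fold. The SD is 1.09 for senescent shcontrol over control, whose anchor sets differ (0.66 over anchors with the same ends), 0.45 for shMETTL3 and 0.48 for shMETTL14 over shcontrol.

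Among the 10 highest anchors in shMETTL3 were those on chromosome 13 from 111613803 to 111621273 (87 against 24 PETs, log2 ratio 1.66), chromosome 15 from 74672859 to 74679310 (91 against 26, 1.61), chromosome 16 from 2884448 to 2898941 (133 against 40, 1.54) and chromosome 21 from 44911887 to 44924236 (214 against 69, 1.45). A second chromosome 13 anchor, from 111590280 to 111597890, had 83 against 28 PETs and a log2 ratio of 1.37. Besides those on chromosome 4, the 10 lowest included anchors on chromosome 8 from 16216909 to 16225634 (31 against 77 PETs, -1.47), chromosome 7 from 78582545 to 78594006 (31 against 72, -1.37) and chromosome 2 from 173555532 to 173570266 (33 against 75, -1.34).

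In shMETTL14 the 10 highest anchors included those on chromosome 3 from 127602544 to 127613582 (117 against 19 PETs, log2 ratio 1.83), chromosome 16 from 82731271 to 82736471 (109 against 21, 1.59) and chromosome 12 from 66330952 to 66360069 (289 against 63, 1.43). The 10 lowest included a pair on chromosome 6, from 74956713 to 74968497 (82 against 141 PETs, -1.53) and from 74991608 to 75002438 (72 against 120, -1.49), a pair on chromosome 17, from 79314079 to 79321684 (49 against 84, -1.52) and from 79364682 to 79380718 (78 against 111, -1.26), and chromosome 16 from 86282914 to 86295087 (45 against 77, -1.52). The chromosome 8 anchor from 117002160 to 117008466 was among the 10 lowest in both knockdowns, at -1.12 in shMETTL3 and -1.36 in shMETTL14.

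Whether PETs gained in senescence were lost after knockdown was asked over the 2308 anchors higher in senescent shcontrol than in control. Of these, 60.1% were lower in shMETTL3 and 64.3% in shMETTL14. With no knockdown effect the shared library gave 61.2% (58.6 to 63.6 over 100 simulations) and 62.0% (60.4 to 64.7). With its PETs split into separate parts for choosing and comparing, 50.6% and 54.6% of 1557 anchors were lower, against 54.8% and 53.5% of the 8493 anchors that differed less from control. The median log2 ratios of the 2308 anchors were -0.09 and -0.15, beyond the simulated -0.08 to -0.05 for each, while the anchors that differed less from control had -0.10 and -0.08. With the PETs split they were -0.01 and -0.05, against -0.05 and -0.04. The measures thus differed on whether these anchors returned toward the control, and simulations cover counting error only. Chosen per covered kb, 69.7% and 73.7% of 2453 anchors were lower, above the simulated 66.4% (64.2 to 68.4) and 67.7% (65.7 to 70.0). Of the 367 anchors lower in senescent shcontrol per covered kb, 23.2% and 16.6% were lower again, within the simulated 17.4 to 27.1% and 15.1 to 23.3%. Of the 2324 anchors lower by PETs, 45.4% and 40.7% were lower again, above the simulated 35.8 to 41.3% and 35.1 to 39.7%. With the PETs split, 53.6% and 49.5% of 2141 such anchors were lower, against the 54.8% and 53.5% above.

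The knockdowns shared some of their differences from shcontrol. Over 12114 anchors with enough PETs in both comparisons, 51 met the size rule as higher in both and 32 as lower in both. Independent lists of these sizes would share 1.95 and 2.69, and simulations of the shared shcontrol library with no effect gave at most 10 and 7. The simulation covers only the counting error of the shared library, not other variation of it. The log2 ratios of the knockdowns correlated across 14999 anchors with r = 0.578, and the no-effect simulation gave 0.581. Their covariance was 0.127 against 0.0595 simulated, an excess of 0.0671. With the shcontrol PETs split the covariance was 0.0674 with r = 0.229. The simulated 0.0595 is for the unsplit library and is no reference for the split one, from which shared counting error is removed. Other variation of the shcontrol library stays in both values. Between the knockdown libraries directly, 340 of 16778 anchors were higher in shMETTL14 and 186 lower (64.6% higher, 51.5% under TMM scaling), and 2 were higher and 18 lower with at least 200 PETs. Among named anchors (at least 100 PETs), the highest was chromosome 8 from 16216909 to 16225634 (145 against 31 PETs, log2 ratio 1.62). The lowest of them was chromosome 16 from 86282914 to 86295087 (45 against 102, -1.75). Of 1777 windows, 1 was at least 2-fold lower in shMETTL14, chromosome 3 from 54 to 55 Mb at 0.450 (0.381 to 0.532).

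Called loops numbered 25047 in control, 13388 in senescent shcontrol, 14883 in shMETTL3 and 20711 in shMETTL14. These counts followed depth. With PETs thinned to 552029 but the false discovery rate still that of the full library, they were 16706, 13388, 13634 and 14489, so these are not calls at equal depth. On the PET minimum alone, which needs no such rate, they were 27138, 29625, 30498 and 29694 at equal depth, which put senescent shcontrol above control. The control PETs lie on another anchor set, with 66743 anchors against 53118 in senescent shcontrol. The order of these libraries was therefore not separated from the anchor sets. The step of the deposited false discovery rate with span differed between libraries, as 47.9% of interactions with at least 4 PETs at 100 to 200 kb were called in shMETTL14 (3622 of 7554) and 73.6% in shcontrol (2992 of 4065). The median span of called loops, 139, 94.3, 95.6 and 157 kb in the same order, was 57.3, 94.3, 72.6 and 51.5 kb after thinning with the full-depth rate. Hubs made up 18.2%, 13.8%, 14.9% and 17.1% of anchors with a called loop, and between 13.6% and 14.3% after thinning with the full-depth rate. The anchor that starts at position 76408003 of chromosome 12 had the most called loops in control (45), senescent shcontrol (33) and shMETTL3 (33), and in shMETTL14 an anchor that starts at 4700738 of chromosome 10 had the most (42).

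**Figure D5:**
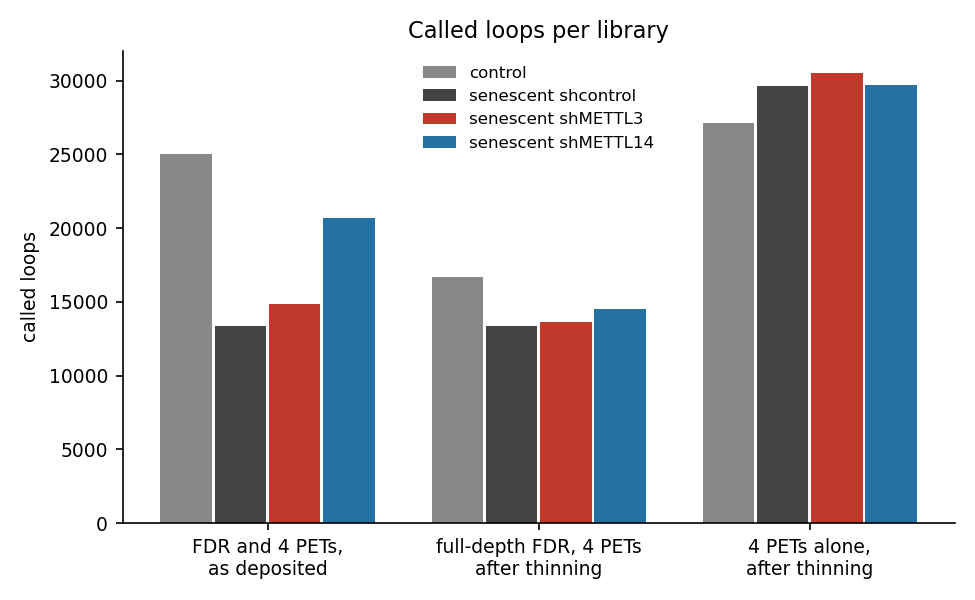
Called loops (vertical axis) in the 4 libraries under 3 rules: the false discovery rate and 4 PETs as deposited, the full-depth rate and 4 PETs after thinning to equal PETs, and 4 PETs alone after thinning. Senescent shcontrol has 13388 against 25047 in control as deposited, and 29625 against 27138 under the last rule. The control uses a different anchor set under every rule.

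Of the called loops of senescent shcontrol, 45.5% (44.6 to 46.3) were also called in control, and 78.1% (77.4 to 78.8) matched any interaction there. The control uses another anchor set, and with at least 50% of each anchor covered the share called was 24.9% (24.1 to 25.6). Shares between senescent libraries could not move under this rule, since overlapping anchors of their common set are the same anchor. Of the called loops of shMETTL3, 54.7% (53.9 to 55.5) were called in shcontrol, and of those of shMETTL14 43.6% (42.9 to 44.3). In the other direction, 23.2% of control loops were called in senescent shcontrol (22.7 to 23.7), while 60.8% of shcontrol loops were called in shMETTL3 (60.0 to 61.6) and 67.4% in shMETTL14 (66.6 to 68.2). Any interaction of shcontrol matched 94.5% of shMETTL3 loops and 89.8% of shMETTL14 loops. After thinning with the full-depth rate, the shares of loops of senescent shcontrol called in control, and of shMETTL3 and shMETTL14 loops called in shcontrol, were 38.4%, 57.4% and 54.9%. Of 28996 loops called in any senescent library, 6961 were called in all 3.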

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

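The tests in this part were chosen after the span profiles had been seen, and their outcomes were not known when they were chosen. In 3 ranges of span, and in the sum of the longest of them, the share of PETs was on opposite sides of senescent shcontrol in the knockdown libraries, with counting intervals that exclude 1 in each. The difference between the knockdowns was not tested against the spread between cultures, since each group has 1 library. At 50 to 100 kb shMETTL3 stood at 1.04 of shcontrol (1.03 to 1.05) and shMETTL14 at 0.974 (0.966 to 0.983), and shMETTL14 over shMETTL3 was 0.939 (0.932 to 0.947). At 500 to 1000 kb they stood at 0.891 (0.879 to 0.902) and 1.04 (1.02 to 1.05), a ratio of 1.16 (1.15 to 1.18). At 1000 to 2000 kb they stood at 0.817 (0.805 to 0.830) and 1.05 (1.04 to 1.07), a ratio of 1.29 (1.27 to 1.30). At 500 kb or more in all they stood at 0.860 (0.852 to 0.869) and 1.04 (1.03 to 1.05), a ratio of 1.21 (1.20 to 1.22).

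The ratio at 500 kb or more was below 1 in shMETTL3 on 23 of 23 chromosomes and above 1 in shMETTL14 on 20 of 23, which argues against a few chromosomes as the source of either part. In interactions of at least 4 PETs at equal depth, shMETTL3 stood at 0.754 of shcontrol (0.719 to 0.790). Its lower share was thus not confined to thinly supported interactions. Such interactions held only 3966 of the 80937 shcontrol PETs at 500 kb or more, so thinner ones may still hold most of the difference. The ratio for shMETTL14 in interactions of at least 4 PETs at equal depth was 0.992 (0.949 to 1.04), so its higher share may come from thinly supported interactions. Without thinning, at unequal depth, that ratio was 1.43 (1.38 to 1.48). Differences in ligation or library preparation between single cultures stay open for both parts, as does an effect of the knockdown itself.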

How the results depend on the processing

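Calling without the false discovery rate, counting both ends in shared anchors, restricting to the same ends and dividing by covered length were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The windows around transcription starts and the gene lists were not run, since no annotation of hg19 was in hand. Of the alternative values of the comparisons, 83 stayed within the counting interval or within 1.5 times of a count, 112 moved beyond it and 9 reversed. All 600 alternative log2 ratios of the 80 named anchor comparisons had the sign given in the report. These anchors were chosen for extreme ratios and the alternatives reuse the same PETs, so a change of sign was unlikely from the start. Except where fewer interactions or anchors entered by construction, the cause was not tested. Depth limited called loops and hubs. Thinning kept the false discovery rate of the full library, so only thinning with 4 PETs alone compares libraries at equal depth. The control still uses another anchor set there. Values are in the order senescent shcontrol over control, shMETTL3 over shcontrol, shMETTL14 over shcontrol and shMETTL14 over shMETTL3.

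Ratios of called loops were 0.535, 1.11, 1.55 and 1.39 as reported. They were 0.572, 1.06, 1.50 and 1.41 with at least 2 PETs, and 0.553, 1.13, 1.48 and 1.31 with at least 8. With a false discovery rate of at most 0.0001 they were 0.482, 1.15, 1.71 and 1.50. After thinning they were 0.801, 1.02, 1.08 and 1.06. With 4 PETs alone they were 0.532, 1.19, 1.80 and 1.52, and with 4 PETs alone after thinning 1.09, 1.03, 1.00 and 0.974, so that senescent shcontrol over control and shMETTL14 over shMETTL3 reversed. Ratios of the hub share were 0.757, 1.08, 1.24 and 1.15 as reported, and 0.679, 1.15, 1.33 and 1.15 with at least 8 PETs. After thinning they were 0.965, 1.01, 0.984 and 0.970, with 4 PETs alone 0.678, 1.14, 1.49 and 1.31, and with both changes 1.06, 1.03, 0.980 and 0.950. Both shMETTL14 ratios of hubs reversed after thinning and with both changes, and senescent shcontrol over control reversed with both changes.

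Ratios of the share of PETs at 100 kb or more were 0.982, 0.920, 0.967 and 1.05 as reported. They were 1.01, 0.940, 0.979 and 1.04 over spans of 20 kb or more, where senescent shcontrol over control reversed. In interactions of at least 2 PETs they were 0.911, 0.901, 1.01 and 1.12, where shMETTL14 over shcontrol reversed, and in those of at least 8 PETs 0.737, 0.887, 0.936 and 1.06. With both ends in shared anchors they were 0.972, 0.914, 0.960 and 1.05.

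The percentages of called loops of the first library also called in the other were 45.5, 54.7, 43.6 and 47.2 as reported. They were 37.8, 39.9, 31.3 and 32.7 with at least 2 PETs, and 46.9, 62.2, 52.2 and 57.7 with at least 8. With a false discovery rate of at most 0.05 they were 48.1, 56.0, 45.3 and 48.6, and at 0.0001 they were 45.0, 51.7, 38.8 and 42.5. After thinning they were 38.4, 57.4, 54.9 and 57.7, with 4 PETs alone 52.0, 56.3, 43.8 and 50.2, and with both changes 37.8, 60.2, 60.2 and 62.2. With at least 50% of each anchor covered, 24.9% of the loops of senescent shcontrol were found in control. With anchors within 5 kb the percentages were 54.3, 64.1, 52.2 and 55.0.

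Anchors higher and lower by the size rule were 2308 and 2324, 229 and 162, 451 and 221, and 340 and 186 as reported. Over called interactions alone they were 865 and 1282, 107 and 73, 167 and 116, and 127 and 101. With at least 20 PETs they were 4644 and 3637, 778 and 778, 1097 and 824, and 1020 and 677. Simulated counting error alone gave 487, 527, 561 and 611 anchors at that minimum, higher and lower together. With at least 200 PETs the observed anchors higher and lower were 293 and 293, 10 and 3, 5 and 14, and 2 and 18. Over spans of 20 kb or more, 151 anchors were higher in shMETTL3 than in shcontrol and 221 higher in shMETTL14 than in shMETTL3, and with a pseudocount of 5 per 1000000 the latter were 204. For senescent shcontrol against control, 1396 were higher with both ends in shared anchors, 367 were lower per covered kb, 162 were higher and 15 lower of 829 with the same ends, and 0 and 0 of 10 with the same ends on both sides.

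Of the anchors higher in senescent shcontrol than in control, 60.1% were lower in shMETTL3 and 64.3% in shMETTL14 as reported. For shMETTL3 this was 57.9% under median-of-ratios scaling and 53.8% under TMM. For shMETTL14 it was 67.7% over called interactions and 61.7% with at least 20 PETs. With at least 200 PETs it was 57.7% and 76.1%, with the shared library split 50.6% and 54.6%, and per covered kb 69.7% and 73.7%. The correlation between the knockdowns, 0.578 as reported, was 0.229 with the shared library split. The split removes shared counting error by construction, but each part holds fewer PETs, which adds counting error of its own. These influences on the correlation were not separated.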

Other observations

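The tests of counting error, of anchor ends, of partner anchors and of the shared shcontrol library in this part were chosen after the results they address had been seen, while the test without a single anchor was chosen before its outcome was known. By whole chromosome, chromosome 8 held 1.19 times the control share of PETs in senescent shcontrol (1.17 to 1.20) and chromosome 22 held 0.809 (0.787 to 0.832). Relative to senescent shcontrol, chromosome 17 stood at 0.945 in shMETTL3 (0.929 to 0.962) and 0.890 in shMETTL14 (0.876 to 0.905), and chromosome 22 at 1.00 (0.971 to 1.03) and 0.904 (0.878 to 0.931).

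Several more windows that were at least 2-fold higher in senescent shcontrol than in control were lower in both knockdown libraries, and all windows in this paragraph were picked after their values were seen. On chromosome 12, the windows from 62 to 63 and from 63 to 64 Mb stood at 0.660 (0.502 to 0.865) and 0.643 (0.546 to 0.756) of shcontrol in shMETTL3, and at 0.635 (0.496 to 0.812) and 0.687 (0.596 to 0.793) in shMETTL14. On chromosome 2, the window from 146 to 147 Mb stood at 0.783 (0.698 to 0.879) in shMETTL3 and 0.679 (0.609 to 0.756) in shMETTL14. On chromosome 1, the window from 199 to 200 Mb stood at 0.788 (0.703 to 0.884) and 0.735 (0.661 to 0.817). The window on chromosome 11 from 128 to 129 Mb was higher in both, at 1.20 (1.11 to 1.30) and 1.30 (1.21 to 1.39). The window on chromosome 6 from 27 to 28 Mb, which was lower in senescent shcontrol than in control, was lower again at 0.596 (0.495 to 0.715) in shMETTL3 and 0.625 (0.532 to 0.735) in shMETTL14. The highest window ratio was 1.77 in shMETTL3 (1.39 to 2.26), on chromosome 16 from 46 to 47 Mb, and 1.92 in shMETTL14 (1.52 to 2.46), on chromosome 1 from 116 to 117 Mb.

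The window on chromosome 4 from 74 to 75 Mb was lower in both knockdown libraries than in senescent shcontrol. The upper bounds of the ratios reach at most 0.758, which argues against counting error, and without the anchor from 74582038 to 74608665, the one with the largest deficit, shMETTL3 stood at 0.588 of shcontrol (0.535 to 0.646), which argues against a single anchor. A high value of the shared senescent shcontrol library alone and an effect of both knockdowns cannot be told apart: shMETTL14 over shMETTL3 was 1.26 (1.17 to 1.36), a log2 ratio of 0.33 within 2 SD of all windows (SD 0.24). A lower share of PETs in this window after knockdown of METTL3 or METTL14 is a hypothesis that further cultures could test. Contact and acetylation were not separated in it.

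Of the shared anchors with at least 50 PETs, 30.7% were at least 2-fold apart between control and senescent shcontrol. Counting error alone gave 0.463%, and counting only PETs with both ends in shared anchors still gave 27.9% (27.1 to 28.7), which argues against counting error, and against partners held by 1 anchor set alone as the whole cause. Among anchors with the same ends in both sets, centred on their median, 11.9% (9.81 to 14.3) met the size rule, against at most 4.05% (2.93 to 5.44) of such anchors between senescent libraries, which argues against different ends of the anchor itself as the whole cause. Anchor length may still account for a part (correlation of covered length and PET ratio 0.776). Length may also follow the change in PETs, and the direction was not tested. Different ends of the partner anchors stay open. With the same ends on both sides only 10 anchors had enough PETs, of which 0 met the rule. Senescence, the separate calling of anchors and the preparation of single libraries were not separated by this design. The label used for the control library names no hairpin, so carrying a hairpin was not separated from senescence either.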
